A study of Homo sapiens with 4 samples.

How the data were processed

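The samples were 4 CUT&RUN libraries of GATA4 in PaTu8988S, an established cell line derived from a pancreatic adenocarcinoma. CUT&RUN maps where a protein sits on DNA: an antibody bound in permeabilised cells recruits a micrococcal nuclease, and the DNA fragments it releases are sequenced. Per the labels' protocols, each library used 500000 cells and 10 ug of an anti-GATA4 antibody (MAB2606), DNA carrying a spike-in was recovered from the supernatant, and the libraries were sequenced in paired-end mode with an average fragment of 325 bp, of which 120 bp was adaptor. All 4 libraries formed 1 group. The labels number them 1 to 4 and do not say whether they came from separate cultures. An untreated, untargeted-antibody or input control was not analysed here.

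The data analysed were 1 list of genomic intervals, which the labels describe as the peaks common to the 4 libraries. The deposited list holds 3 columns: chromosome, start position and end position. Its positions are in bp, and neither a score, a signal, a count nor a gene name accompanies an interval. Per the submitters' processing notes, SEACR (a peak caller made for CUT&RUN) and HOMER (a peak annotation and motif package) were used with genome build hg19; versions and parameters are not given in the sources used here, nor is the overlap that made a peak common. Because the 4 libraries are pooled in the list, the spread between libraries, the depth behind an interval and the effect of leaving out a library could not be measured, and the errors given below describe variation along the genome only. Read depth per library is unknown.

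The file held 21308 intervals and 1 blank line, with 0 duplicated and 0 overlapping intervals. The analysis used the 21139 intervals on the 22 autosomes and chromosome X (99.2%). Positions are given as in the file. Whether starts are counted from 0 or from 1 is not stated: the mitochondrial interval runs from 1 to 16571. Widths are end minus start, so an interval may be 1 bp wider than stated.

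The build was checked against a RefSeq gene table of the GRCh38.p14 assembly. Distances between interval centres and the ends of protein-coding genes were counted in 1 kb steps out to 2 Mb on either side. On 0 of 23 chromosomes was the count highest at a distance of 0, although on 5 it was at least 2 times the median over distances. This check does not settle the build, since how far these intervals pile up at gene ends in their own build was not tested. The intervals were treated as hg19 because the submitters' processing notes state it, and coordinates of the other build were not used. An hg19 sequence and annotation were not used here. The planned tests of promoter overlap, GATA, FOXA and other motifs, genes near peaks, and the 15 gene lists (classical and basal-like pancreatic cancer genes, endoderm regulators, epithelial junction, gastric, intestinal, hepatic, acinar, endocrine, mesenchymal, cardiac, haematopoietic, neuronal, ribosomal and Hippo pathway genes) need them and were not run, and no interval is assigned to a gene. The comparison of strong with weak peaks was not run either, as it rested on motifs and promoters. The table was used otherwise only for the chromosome of GATA4 and GATA6.

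What was computed rests on positions alone, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals no more than 12.5 kb apart were linked into clusters, and clusters of 3 or more were counted. The count was compared with 1000 random placements of all intervals on their own chromosomes, between its first and last interval, with widths kept; stretches without any interval were not avoided and random intervals could overlap. A two-sided permutation p was taken from the distance to the mean of the placements. Clusters of 20 or more intervals were called dense tracts, a limit chosen after seeing the data, and tracts less than 1 Mb apart were joined into regions. Interval density per chromosome is the number of intervals divided by the distance from the first to the last one, with a 95% bootstrap interval from 10000 draws of its 5 Mb windows. Each chromosome's 5 Mb windows were compared with all others by permuting windows between them (20000 permutations, two-sided), with Benjamini-Hochberg adjustment over 23 chromosomes. Widths inside tracts were compared with widths elsewhere by permuting the median widths of tracts and of 5 Mb windows (100000 permutations, two-sided, on the log2 scale). Pearson and Spearman correlations were tested with 100000 permutations. Adjacent 5 Mb windows were compared by Spearman correlation against 1000 reorderings of the windows within chromosomes. Neighbouring windows are not independent, so permutation p values that treat windows as exchangeable are too small where counts run together along a chromosome.

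Peaks were named by a rule fixed before the data were examined: the 10 widest intervals by position, width standing in for the missing score. The comparisons of chromosomes, windows and dense tracts were added after the data were seen, in place of those that need a genome, and the regions and split points within chromosomes were chosen after their values were seen. Only the number and width of intervals and the cluster test were set before the data were examined. The cluster test departed from its plan, which was to keep random placements off bases missing from the genome sequence. Placements could fall in such places, which can lower the random count. The alternatives were merging intervals within 1 kb, the intervals at or above the median width, other linking distances, other limits for a tract, leaving out dense tracts or chromosome 2, other window sizes, and random placement within each interval's own 1 Mb window. The tract search was tested on simulated data with 20940 intervals placed at random: it found 0 tracts without planted ones, 19 of 20 planted tracts of 40 intervals in 100 kb, 2 of 20 with the same number in 300 kb, and 0 false ones. The simulated intervals were spread evenly along each chromosome, unlike those of the list, so false tracts in dense surroundings were not tested. The label permutation gave p under 0.05 in 5.5% of simulated comparisons of independent values without a difference.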

Results

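Occupancy of GATA4, a zinc-finger transcription factor of endoderm and heart, was mapped by CUT&RUN in 4 libraries of the pancreatic adenocarcinoma line PaTu8988S. The series asks how GATA4 and its paralogue GATA6 relate to the classical expression programme of pancreatic ductal adenocarcinoma. The values below describe the single list of intervals common to the 4 libraries. As the list is pooled and no other group accompanies it, the comparisons are between parts of the genome, with no spread between libraries. Positions are those of build hg19.

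The list held 21139 intervals on the 22 autosomes and chromosome X, which together covered 15.7 Mb. The median interval was 586 bp wide, the quartiles were 416 and 859 bp, and the 5th and 95th percentiles were 260 and 1636 bp. The narrowest interval was 68 bp and the widest 32214 bp; 53 intervals were 5 kb or wider and 24 were 10 kb or wider. The median distance between neighbouring intervals was 15.5 kb, with quartiles of 2.37 and 88.4 kb.

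Most of the widest intervals lay in 1 place. Width stands in for a score here, and no control library was analysed that would show whether these widths are particular to GATA4. Of the 10 widest, 8 were on chromosome 2 between positions 15860437 and 16588282, a stretch of 728 kb. The widest of all ran from 15915914 to 15948128 (32214 bp). The next ran from 16187624 to 16216371 (28747 bp), from 16076309 to 16100967 (24658 bp), from 15968260 to 15992112 (23852 bp) and from 16364436 to 16388157 (23721 bp). The remaining 3 there ran from 16567028 to 16588282 (21254 bp), from 16227911 to 16247781 (19870 bp) and from 15860437 to 15879626 (19189 bp). The stretch held 21 intervals, which covered 48.2% of it, and their median width was 15608 bp, against 494 bp for the other 923 intervals of chromosome 2. The 2 other members of the 10 widest ran from 36778255 to 36800944 on chromosome 19 (22689 bp) and from 46416470 to 46435764 on chromosome 16 (19294 bp). The chromosome 16 interval begins where that chromosome's longest stretch without an interval (11.1 Mb) ends.

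Chromosomes differed widely in how many intervals they carried. Chromosome 20 was the densest, with 1832 intervals or 29.3 per Mb (95% bootstrap interval 12.6 to 52.1 over its 13 windows). It was followed by chromosome 21 with 20.8 per Mb (2.18 to 46.3), chromosome 19 with 16.3 (6.35 to 33.2), chromosome 18 with 14.2 (2.80 to 31.5) and chromosome 8 with 13.5 (8.05 to 21.5). GATA6 is a gene of chromosome 18 and GATA4 of chromosome 8, but no interval was assigned to either gene. Where these genes lie relative to the dense parts of their chromosomes was not examined. The sparsest were chromosome X with 1.70 per Mb (0.974 to 2.74) and chromosome 22, where 78 intervals gave 2.22 per Mb (1.05 to 3.85). The densest chromosome thus held 17.3 times as many intervals per Mb as the sparsest. Chromosome 20 alone passed the test against all others, with a mean of 141 intervals per 5 Mb window against 32.6 elsewhere (permutation test, p = 0.00015, adjusted p = 0.00345 over 23 chromosomes). For chromosomes 8, 18, 19 and 21 the permutation p was 0.014, 0.04, 0.033 and 0.035 and the adjusted p 0.138 each. Without the dense tracts described next, chromosome 20 still held 19.5 per Mb (permutation test, adjusted p = 0.00115), chromosome 8 held 11.2 (permutation test, adjusted p = 0.0046), and chromosomes 18, 19 and 21 held 5.23, 8.39 and 6.70 (permutation test, adjusted p = 0.898, 0.203 and 0.972). Without the tracts chromosomes 11 and 13 also lay above the rest, at 9.71 and 10.5 per Mb (adjusted permutation p = 0.0253 and 0.046), and chromosomes 4 and X below it, at 2.22 and 1.24 (adjusted permutation p = 0.0253 and 0.0138). With all intervals the adjusted permutation p of chromosomes 11, 13, 4 and X was 0.245, 0.431, 0.138 and 0.138. Neighbouring windows are not independent, so the p values of these tests are too small where counts run together.

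**Figure D1:**
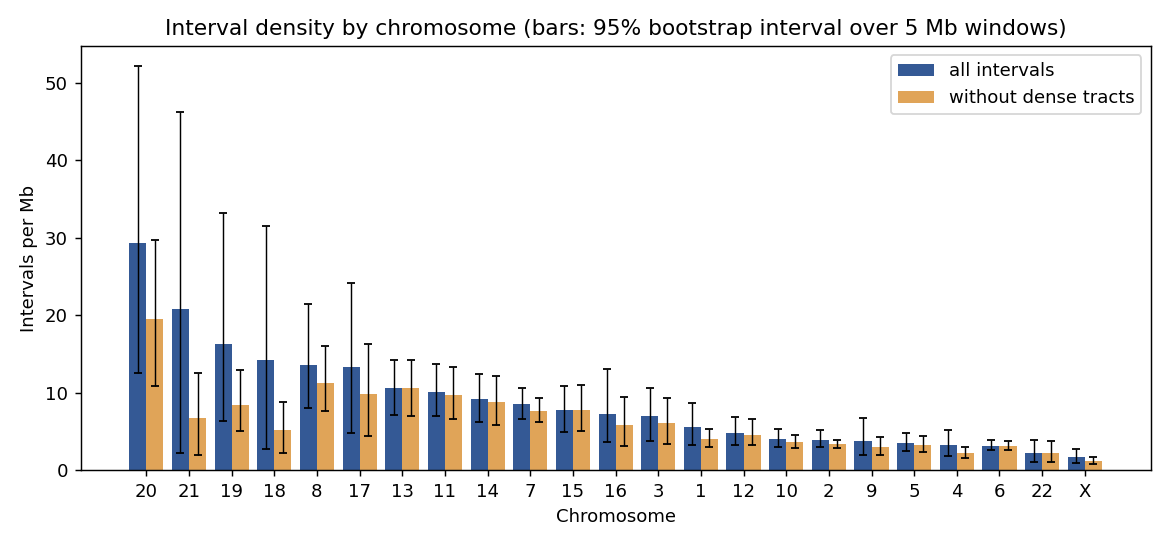
Intervals per Mb (y axis) for each chromosome (x axis, ordered by density), for all intervals (blue) and without the dense tracts (orange), with error bars that give the 95% bootstrap interval over 5 Mb windows. Chromosome 20 stands highest at 29.3 per Mb, and chromosome 21 falls from 20.8 to 6.70 per Mb once its tracts are left out.

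Within chromosomes the intervals were concentrated in short stretches. Of 606 windows of 5 Mb, 42 held 100 intervals or more, and these together held 8899 intervals (42.1%), while the median window held 16 (quartiles 8 and 34). The fullest windows were on chromosome 20 from 50 to 55 Mb (664 intervals), chromosome 18 from 20 to 25 Mb (589), chromosome 8 from 140 to 145 Mb (527) and chromosome 19 from 35 to 40 Mb (511). Adjacent windows resembled each other: their counts had a Spearman correlation of 0.51 over 583 pairs of windows, against a mean of 0.23 when windows were reordered within chromosomes (permutation p = 0.001, the smallest that 1000 reorderings can give).

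Parts of several chromosomes differed in level, with the dividing points read by eye from the windows and no test made. Levels also varied within the parts, as on chromosome 8, whose windows held 5 intervals from 30 to 35 Mb and 95 from 35 to 40 Mb, and chromosome 20, with 51 from 20 to 25 Mb and 134 from 25 to 30 Mb. Chromosome 18 carried 1037 intervals up to 25 Mb (41.5 per Mb) and 68 beyond it (1.29 per Mb). Chromosome 3 carried 947 intervals in its last 32.9 Mb (28.8 per Mb) and 399 before it (2.48 per Mb). Chromosome 8 held 691 intervals from 140 Mb on (110.0 per Mb), against 9.20 per Mb before, and chromosome 20 held 93.3 per Mb from 50 Mb on, against 12.55 before. Chromosome 9 was nearly empty up to 30 Mb, with 13 intervals (0.434 per Mb), against 4.72 per Mb beyond. Outside the dense tracts the ratios of the denser to the sparser part were 10.6 on chromosome 18, 12.9 on chromosome 3, 7.17 on chromosome 8, 5.37 on chromosome 20 and 8.57 on chromosome 9.

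**Figure D2:**
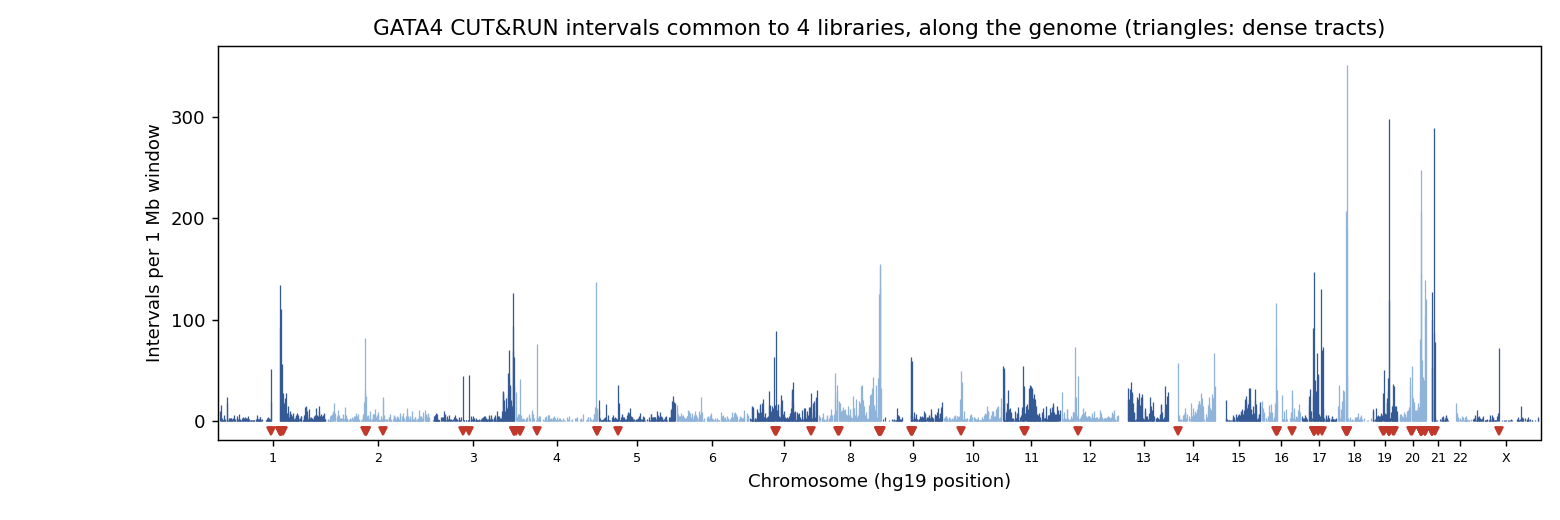
Number of intervals in each 1 Mb window (y axis) along chromosomes 1 to 22 and X (x axis, hg19 positions, shades alternating by chromosome), with red triangles at the dense tracts. The highest window, on chromosome 18 from 21 to 22 Mb, holds 351 intervals, followed by chromosome 19 from 39 to 40 Mb with 298 and chromosome 21 from 16 to 17 Mb with 289.

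The intervals formed 1076 clusters of 3 or more, which held 9535 intervals (45.1%), while 8540 intervals (40.4%) had no neighbour within the linking distance. Random placement on the same chromosomes gave 384 ± 16.4 such clusters (mean and SD of 1000 placements, range 328 to 434), so the observed number was 2.80 times higher (two-sided permutation p = 0.001, the smallest that 1000 placements can give). The ratio depended on the setting: it was 10.5 with a linking distance of 5 kb, 1.34 with 25 kb, 5.54 for the intervals at or above the median width and 5.80 without the dense tracts. Clusters were not recounted after merging intervals within 1 kb, and 983 gaps were 100 bp or shorter. How far split pieces of a single stretch add to the excess was thus not tested. When every interval was placed at random within its own 1 Mb window, an alternative chosen after seeing the data, 1108 ± 21.5 clusters arose, and the observed number was 0.97 times that (permutation p = 0.13). This placement keeps the window counts that the clusters themselves set, and a dense tract counts as 1 cluster when observed but can break into several when scattered. Without the dense tracts, the remaining 16682 intervals formed 980 clusters, 1.42 times the 692 ± 17.6 of placement within 1 Mb windows (permutation p = 0.001). Random intervals could fall on the ground of the left-out tracts, where no remaining interval lies, which can lower the random count.

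Dense tracts, which are clusters of 20 intervals or more, numbered 96 on 19 chromosomes. They held 4457 intervals (21.1% of the list) in 13.3 Mb, with a median length of 100.7 kb. The limit of 20 was chosen after seeing the clusters. Count and share depend on the limits set: merging intervals within 1 kb first left 39 tracts with 9.04% of intervals, a linking distance of 5 kb gave 7.54% and a limit of 50 intervals 11.3%. Intervals covered between 12.2% and 59.7% of a tract, with a median of 28.4%. The largest tract, on chromosome 21 from 16306228 to 17216982, held 346 intervals in 911 kb. The next were on chromosome 18 from 21466132 to 22104860 (264 intervals), chromosome 19 from 39264410 to 39901666 (235), chromosome 20 from 49868615 to 50453003 (195) and chromosome 18 from 20704190 to 21163908 (151 intervals, 59.1% covered). Joined across gaps of up to 1 Mb, 7 tracts of chromosome 18 formed a region from 19477291 to 22104860 with 775 intervals, which is 70.1% of that chromosome's total. On chromosome 20, 8 tracts from 49868615 to 52851321 held 638 intervals with those between them (34.8% of the chromosome), and on chromosome 8, 9 tracts from 142163855 to 145781501 held 528 (26.7%). Chromosome 19 had a region of 391 intervals from 38528381 to 39901666 (40.7%). Further regions lay on chromosome 17 from 26785232 to 27489812 (162 intervals) and from 45761133 to 46140347 (115), on chromosome 1 from 142535430 to 143541233 (219), on chromosome 21 from 9825432 to 11108206 (222) and on chromosome 4 from 190470705 to 190982576 (133). The chromosome 1 region begins where that chromosome's longest stretch without an interval (21.1 Mb) ends. The wide intervals of chromosome 2 near 16 Mb are not among the tracts, since gaps longer than the linking distance part them.

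**Figure D3:**
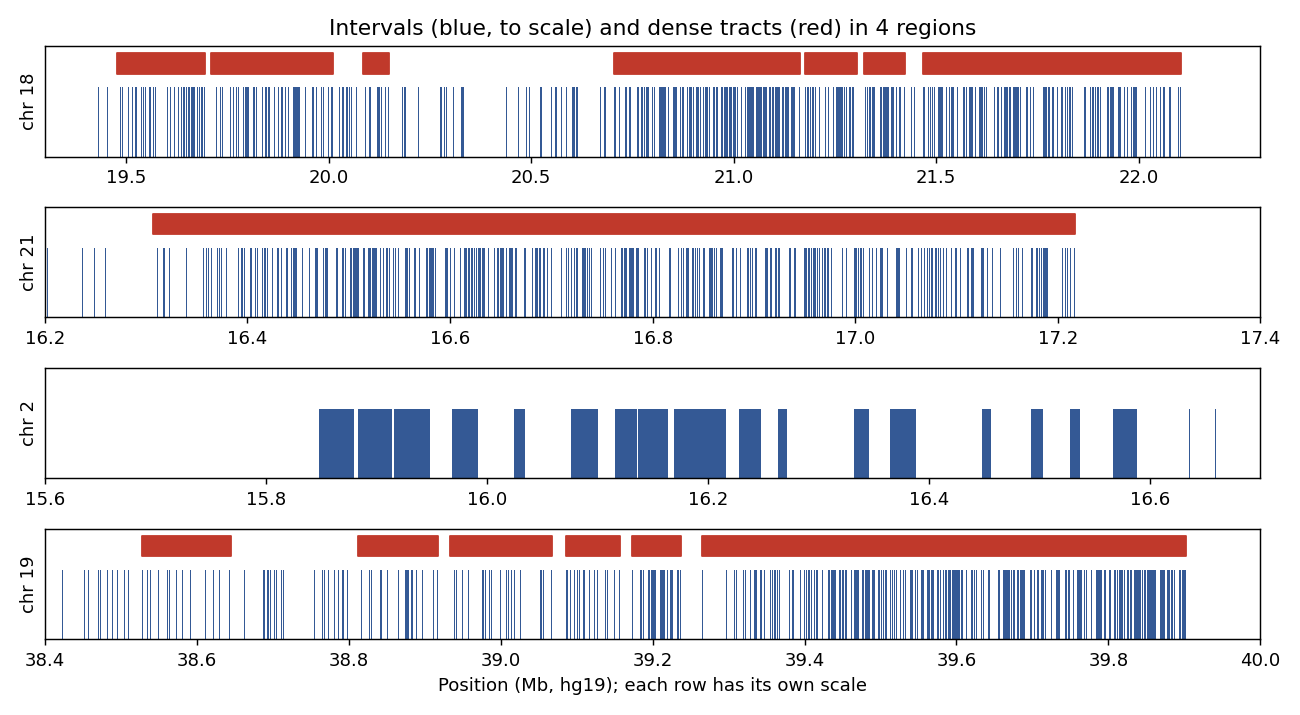
Maps of 4 regions on chromosomes 18, 21, 2 and 19 (x axis, position in Mb, hg19, a separate scale for each row), with each interval drawn to scale in blue and each dense tract as a red bar. Chromosome 21 shows 346 intervals in 1 tract, and chromosome 2 shows fewer intervals that are far wider.

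Pooled over all tracts, intervals inside dense tracts were wider than those elsewhere. Their median width was 764 bp, against 558 bp for the 16682 intervals outside, a ratio of 1.37. Merging intervals within 1 kb gave 2.22, but merging by itself widens intervals where they are dense. The 851 intervals of the 23 tracts within 5 Mb of their chromosome's longest interval-free stretch had a median of 547 bp, below that outside tracts. Those of the other 73 tracts, 3606 intervals, had a median of 816 bp, so the pooled ratio mixes tracts on both sides of 558 bp. The median width of 70 of the 96 tracts lay above 558 bp, and the test of tract medians against the medians of 592 windows elsewhere gave a permutation p of 1e-05, the smallest that 100000 permutations can give. Windows counted equally however few intervals they held, and the median of their medians was 491.5 bp. Widths in tracts were not compared with those in their own surroundings. The test took each tract as a separate unit, although the 96 tracts lay in 48 regions, so its p is too small where neighbouring tracts are alike. Region medians lay on both sides of 558 bp, from 270 bp on chromosome 5 to 1425 bp on chromosome 17. Widths were not retested with joined regions as units. Width and density also went together between chromosomes. Over the 23 chromosomes, intervals per Mb and median width had a Pearson r of 0.81 (permutation p = 3e-05) and a Spearman rho of 0.92 (permutation p = 1e-05). Without chromosomes 20 and 21, the farthest from the median density, r was 0.90 (permutation p = 1e-05). With the dense tracts left out, r was 0.80 and rho 0.88 (permutation p = 1e-05 for both). Over all intervals chromosome 18 had the widest, with a median of 831 bp, and chromosome X the narrowest, with 398 bp. Chromosome 22 had a median of 450 bp. Without the dense tracts the median of chromosome 18 was 573 bp, below the 652 bp of chromosome 20, and that of chromosome X was 437 bp.

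**Figure D4:**
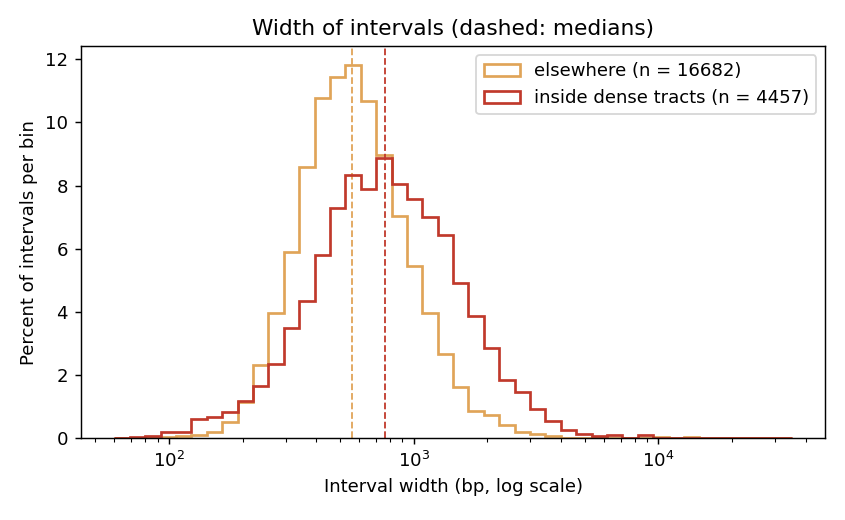
Distribution of interval width (x axis, bp, log scale) as percent of intervals per bin (y axis), inside dense tracts (red, 4457 intervals) and elsewhere (orange, 16682 intervals), with dashed lines at the medians. The median is 764 bp inside tracts and 558 bp elsewhere.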

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

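The results on dense tracts, chromosomes and windows, with their alternatives, placement within 1 Mb and leaving out tracts were chosen after seeing the data; merging for number and width, and for clusters the intervals at or above the median width and the other linking distances, were set before the data were examined. Of 38 recomputed values, 28 kept their direction and side of the threshold or, for counts, stayed within 1.5 times; 9 moved further and 1 reversed. The excess of clusters over random placement was 0.97 when intervals were placed within their own 1 Mb window, which keeps the window counts that the clusters set and breaks up dense tracts, so it does not show what the excess comes from; under the other settings it lay between 1.34 and 10.5. Clusters numbered 588 among the intervals at or above the median width, where fewer intervals were counted. Dense tracts, 96 in the report, numbered 200 with 10 intervals or more, 22 with 50 or more, 48 with a linking distance of 5 kb, 39 after merging intervals within 1 kb and 41 at or above the median width. Their share of intervals, 21.1%, was 11.3% with 50 or more, 7.54% with 5 kb and 9.04% after merging. The width ratio inside tracts lay between 1.33 and 1.502 under the 6 alternatives without merging, each past its threshold with tracts taken as separate units. The 2.22 after merging is no support, as merging widens dense intervals by construction. Alternatives on promoters, motifs, nearby genes, gene lists and strong against weak peaks were not run, as they need an hg19 sequence or annotation, and a stricter score had no score to use. Leaving out each library could not be tried on a pooled list. Depth is unknown, so an empty stretch shows only that no interval common to the 4 libraries was listed there.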

Other observations

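The list included 1 interval over the whole mitochondrial chromosome, from 1 to 16571. Very small gaps were common: 983 of 21116 gaps between neighbouring intervals were 100 bp or shorter, against 438 longer than that and up to 200 bp, and 16 were 1 bp. The longest stretches with no interval were on chromosome 9 from 45364020 to 66459247 (21.1 Mb), chromosome 1 from 121480526 to 142535430 (21.1 Mb) and chromosome 16 from 35285060 to 46416470 (11.1 Mb).

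Chosen after the results were seen were the limit for a dense tract, the test of widths in tracts, both placements of tracts outside empty stretches, the widths and surroundings of tracts near and away from such stretches, the surroundings of joined regions and the limit of 5 intervals per window. The tests of tract surroundings, of placement anywhere on the chromosome, of density without tracts and of count against width over all windows were set out before their results.

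The first pattern is the dense tracts. A candidate explanation is copy-number gain, which raises fragment counts over a wider region: the median density within 500 kb of a tract, outside all tracts, was 6.25 times that of the rest of its chromosome (above 1 for 87 of 96 tracts, 0.50 at random places, some of them in empty stretches), 4.05 times for the 23 tracts near an empty stretch and 6.54 times for the 73 others, but 3.16 times once tracts within 1 Mb were joined and the ground between them left out (above 1 for 41 of 48 regions, 0.51 at random places; permutation p = 0.001 for the first and last, the smallest possible). Edges could be sharp, though a fall there is partly built in, since a region ends with a tract. On chromosome 18 the last 500 kb of the region held 219 intervals and the next 500 kb 0, with 19 in the 500 kb before the region. The counts inside and beyond the end were 201 and 0 on chromosome 19 and 194 and 1 on chromosome 21 from 16306228, but 63 and 58 on chromosome 8. A ratio over both sides does not show this, and its bearing on copy-number gain was not tested. For repeats beside assembly gaps, with the longest interval-free stretch of a chromosome standing in for a gap, the placement set out first gave 23 of 96 tracts within 5 Mb of it and a mean of 16.5 at random (permutation p = 0.11, fewer tracts in 92.9% of placements). That placement let tracts fall inside the empty stretch, where none can lie, and 2 versions made after that result was seen passed their threshold, in the same direction: 2.06 times the mean of 11.2 with placement outside the stretch, and 13 of 32 tracts against 4.92 on the 7 chromosomes where 1 stretch was at least 1.5 times the next (permutation p = 0.001 for both). Each tract was placed as a separate unit, although the 96 tracts lay in 48 regions. These p values are therefore too small where neighbouring tracts lie together. Repeats remain open for all 96 tracts, since no map of assembly gaps was used to tell which stretches are gaps. Of the 73 tracts away from it, 13 also had a median width under 558 bp and 5 no raised surroundings, though the 3606 intervals of the 73 had a median of 816 bp. Only the longest stretch of each chromosome was used, so a tract beside a shorter one counts among the 73. Tracts with narrow intervals on chromosome X from 61713012 (median 279 bp) and chromosome 5 from 46323525 (270 bp) are among them. Intervals in tracts were 1.37 times as wide as elsewhere, but regions rich in true GATA4 sites would also raise surroundings and widths, and no biological explanation was tested, since there is 1 group and no control library was analysed here.

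The second pattern is the uneven density between chromosomes. The dense tracts alone do not account for it, since the densest chromosome held 15.8 times as many intervals per Mb as the sparsest without them. A difference in signal strength over broad regions, such as copy number gives, may contribute: outside tracts, count and median width had a Spearman rho of 0.59 over 592 windows of 5 Mb and 0.60 over the 518 with 5 intervals or more (permutation p = 1e-05 for both, the smallest possible), while Pearson's r was 0.14 and 0.12. Neighbouring windows are not independent, and true differences in site density or open chromatin could give the same relation. A copy-number profile of PaTu8988S or a control library, neither analysed here, would help to separate these, and would bear on the wide intervals of chromosome 2 near 16 Mb, for which copy-number gain is an untested possibility.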
